A study of Arabidopsis thaliana with 9 samples.

How the data were processed

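Bulk RNA sequencing was analysed from 9 libraries of whole wild-type Arabidopsis thaliana seedlings, ecotype Col-0. Per the labels, seedlings spent 5 days on solid medium and 5 further days in liquid medium before treatment. The 3 groups were mock, flg22 at 100 nM and 2'-aminoacetophenone (2-AA) at 200 uM, with 3 libraries each. Mock libraries carry the label of untreated seedlings. The duration of treatment, the hour of harvest and what mock seedlings received are not given in the sources used here. Libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, per the labels. The series' design text calls the 3 libraries of a group biological replicates and does not say whether they came from separate cultures or days, so p-values measure the spread between these libraries.

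The authors deposited 1 table of raw read counts per gene, with whole-number counts for 32833 loci in 9 columns. Per the submitters' processing notes, reads went through Trimmomatic 0.36, HISAT2 and edgeR with the TAIR10 genome build. The roles and settings of these tools, the counting program, the gene annotation and the use of strand are not given in the sources used here. Reads that could come from either strand or from near-identical copies therefore cannot be told apart by gene, and values of tandem or overlapping genes are uncertain, of which the text marks some. The header of the table holds doubled tabs after some names. With these read as 1 separator it gives 9 names, which were taken in order for the 9 columns of values. No column was left unused, and 0 entries named something other than a gene. Of the loci, 32548 matched a reference table of the TAIR10.1 assembly by locus code, and 7289 had 0 counts in all 9 libraries. Coordinates are those of the TAIR10.1 annotation, counted from 1.

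Library totals ran from 26644996 to 33195007 counts. At these totals, 0 counts of a gene in a library allow up to 0.0904 to 0.113 CPM (counts scaled to a common library total by edgeR), taking 3 counts as the floor. A fold against a group with 0 counts in all its libraries was computed against 3 counts over the group and is given as a lower bound, as is a fold where leaving out 1 library leaves at most 3 counts. Reads carried no molecular identifiers, so floors cover counting error only. Pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom from 5.63 to 31.9 over genes with at least 20 reads, so no pair looked like 1 library deposited under 2 names. This does not show whether the RNA came from separate cultures; all 9 were counted as separate samples by their labels.

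Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 21059 genes. Libraries were scaled by TMM, and all 9 entered 1 quasi-likelihood fit with group means only (glmQLFit, glmQLFTest), so that the groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.118 with 6 residual degrees of freedom. The 3 comparisons were flg22 against mock, 2-AA against mock, and 2-AA against flg22. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes in the text come from this test unless another is named. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F value. CPM values are means over the 3 libraries of a group, with the SD where one is given.

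A set of 25 gene lists was fixed before the data were examined, with 426 entries keyed by locus code. In all, 415 entries were kept and 11 were dropped because the reference table did not give the locus code the name written in the list. There were 15 loci in more than 1 list. Lists were tested with camera in limma 3.58.1 on the edgeR counts, two-sided, with a preset correlation of 0.01, and adjusted over 75 tests (25 lists in 3 comparisons). Camera was repeated with a correlation estimated from the data, a setting in which it also uses only the 6 residual degrees of freedom. Adjusted p-values of lists come from camera. List members were also counted with the adjustment over the list alone.

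Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 8 largest rises and the 8 largest falls among called genes with a log2 fold change of at least 1 either way, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Where fewer than 4 genes qualify in a direction, it takes the 4 with the smallest p. It adds up to 4 called members with the smallest p per list, or 2 members if none was called. A further 12 genes are reported whether called or not (FRK1, CYP81F2, WRKY29, WRKY33, NHL10, PR1, ICS1, PAD3, PDF1.2, FLS2, BAK1 and RBOHD). For the overlap of the treatments it takes the 10 genes called in the same direction in both, and up to 10 called in opposite directions, with the largest value of the smaller of their 2 log2 fold changes. The rule takes more genes than the text names, and which of them to leave out was decided after their values were seen.

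Because both treatments were compared with the same 3 mock libraries, 50 sets of 9 libraries with no change were simulated. All 9 libraries of a set, mock included, were drawn afresh from the mean values of the mock group. Both simulated treatments were compared with the same drawn mock group. The overlap of independent lists was computed beside them. The fit was tested on simulated counts drawn from the real means and library sizes, with 200 changed genes among 21059 and a further list of 20 raised genes. For flg22 against mock, 77% of genes changed by a log2 size of 1 and 94% of those changed by 2 were recovered, and 5.5% of called genes were unchanged. The values were 74%, 95% and 3.16% for 2-AA against mock, and 76%, 95% and 10.6% for 2-AA against flg22. Counts were drawn once per comparison. Far fewer genes were changed in them than the 59.2, 62.2 and 15.8% of genes called in the data. These shares therefore need not hold for the reported calls.

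The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter beyond 1 read, a filter of 5 CPM in 3 libraries, fits of only the groups compared, a replicate block, robust dispersions, a test against a 1.5-fold change, omission of organelle genes, and omission of each library in turn. For lists they also included fry, a self-contained test of whether the genes of a list move one way. Fry does not compare a list with other genes. Against mock, where 59.2 and 62.2% of all genes were called, its calls therefore do not set a list apart. After the data were seen, 2 settings were added for libraries with a raised organelle share. Tables were prepared with Python 3.11.15 and pandas 2.3.3.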

Results

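The 9 libraries held mean totals of 31.6 ± 1.40 (mock), 28.9 ± 1.18 (flg22) and 29.8 ± 2.86 (2-AA), as mean ± SD of counts in units of 1e6, n = 3 each. RBCS1A, a small subunit of Rubisco, took the largest share of counts in each library, from 1.2 to 1.5%. Along the first principal component (67.8% of the variance) the 3 mock libraries lay between -95.4 and -89.8 and the 6 treated ones between 28.6 and 59.4. The second (12.2%) parted flg22 libraries (-36.3 to -34.9) from 2-AA libraries (24.7 to 41.0). The third (5.12%) set 1 library of each group, mock 3, flg22 2 and 2-AA 2, at 21.8, 18.6 and 32.1, with the other 6 below 0. These 3 libraries also had the highest chloroplast share of their groups (0.0980, 0.0743 and 0.241%, against 0.0211 to 0.0281% in the other 6). Where a symbol belongs to more than 1 locus, the one meant is that of the fixed lists; FLS2 is AT5G46330.

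With flg22, 18 of 23 genes of cell-surface receptors and co-receptors were higher than in mock seedlings (camera adjusted p = 2.48e-09, or adjusted p = 0.192 with an estimated correlation). FRK1, a receptor-like kinase gene used as a marker of flagellin perception, rose from 2.46 ± 0.994 to 143 ± 59.0 CPM (mean ± SD, n = 3 each; log2 fold change 5.86, SE 0.35, edgeR adjusted p = 1.56e-08). FLS2, the flagellin receptor gene, rose from 16.4 to 51.9 CPM (1.66, SE 0.11, adjusted p = 5.55e-08). The leucine-rich repeat kinase gene IOS1 rose by 3.08 (SE 0.17, adjusted p = 8.71e-09) and EFR, which encodes the receptor of elongation factor Tu, by 2.22 (SE 0.11). LHCB4.2, a light-harvesting gene, fell by 2.74 (SE 0.15, adjusted p = 8.45e-09), and HSP70 fell by 4.0 (SE 0.20, adjusted p = 4.08e-09). Clock genes differed too: LHY, a morning gene, went from 221 to 6.02 CPM and TOC1, an evening gene, from 29.9 to 232 CPM.

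In all, edgeR called 12457 of 21059 genes (59.2%) at adjusted p under 0.05, 6272 higher and 6185 lower with flg22 than in mock, and 1951 and 2044 of them by at least 2-fold. The largest rises among named genes included COR27 (7.48, SE 0.38), a cold- and clock-regulated gene, FKF1 (7.02, SE 0.16), a blue-light receptor gene of the flowering pathway, PCR1 (7.10, SE 0.61) and HAK5 (6.89, SE 0.51), a potassium transporter gene. GDPD6, which acts in phosphate starvation, fell by 6.74 (SE 0.56). GBSS1, a starch synthase gene, fell by 5.32 (SE 0.24). LHY fell by 5.19 (SE 0.35) and ERF71 by 5.32 (SE 0.49). AT4G19750 had 0 counts in all mock libraries and was at least 163-fold higher with flg22 (at least 85.2-fold without flg22 replicate 1). Mock replicate 3 held 25 counts of COR27 and the other mock libraries 2, so that without it COR27 was at least 1090-fold higher. GDPD6 had 0 flg22 counts outside flg22 replicate 1 and was without it at least 192-fold higher in mock, and ERF71 was at -6.03 without flg22 replicate 2. AT4G12500 rose by 7.15 (SE 0.35), a value that is uncertain because it lies beside near-identical copies. Without mock 3, flg22 2 and 2-AA 2 the count was 10951, and with these 3 libraries as a term in the fit 12574; both settings were chosen after the data were seen.

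Of the 23 measured cell-surface receptors and co-receptors (median log2 fold change 1.33), 1 fell and 4 did not pass. BAK1, a co-receptor, rose by 0.62 (SE 0.07; adjusted p = 0.381 against 1.5-fold). PBL1, a receptor-like cytoplasmic kinase gene, rose by 2.04 (SE 0.07). All 13 cysteine-rich receptor-like kinases rose (median 3.21, camera adjusted p = 3.28e-09, or adjusted p = 0.186 with an estimated correlation), among them CRK13 (6.25, SE 0.30) and CRK45 (3.21, SE 0.14). Most of these genes lie in a tandem cluster, where reads of near copies are hard to assign. All 10 intracellular immune receptors and helpers rose (median 0.96, camera adjusted p = 4.14e-06, or adjusted p = 0.336 with an estimated correlation), for example ADR1-L1 (1.67, SE 0.12) and RPM1 (1.49, SE 0.11). Beside these groups, 10 of 11 clock genes were called, with 6 higher and 4 lower.

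Of 29 early markers of pattern-triggered immunity, 22 rose, 3 fell and 4 did not pass (median 1.51, camera adjusted p = 0.000125, or adjusted p = 0.487 with an estimated correlation). Besides FRK1, CYP81F2, an enzyme gene of indole glucosinolate modification, rose by 1.83 (SE 0.17), PUB22, a ubiquitin ligase gene, by 2.21 (SE 0.18), NHL10 by 1.53 (SE 0.36) and MPK3 by 1.01 (SE 0.08). RBOHD, the oxidase gene of the immune oxidative burst, fell by 0.52 (SE 0.11, with adjusted p = 1 against 1.5-fold, a test that a smaller fall cannot pass). Of 29 WRKY factors, 24 rose and 5 did not pass (median 1.33, camera adjusted p = 2.28e-07, or adjusted p = 0.403 with an estimated correlation), including WRKY54 (4.33, SE 0.29), WRKY51 (4.78, SE 0.39), WRKY29 (1.47, SE 0.20) and WRKY33 (1.3, SE 0.17). Of 24 genes of salicylic acid synthesis and response, 19 rose, 1 fell and 4 did not pass (median 1.41, camera adjusted p = 2.8e-06, or adjusted p = 0.263 with an estimated correlation). CBP60G and SARD1, transcription factors that act on salicylic acid synthesis, rose by 3.47 (SE 0.22) and 4.03 (SE 0.29), the synthase gene ICS1 by 1.13 (SE 0.24) and the pathogenesis-related gene PR1 by 3.88 (SE 0.86, adjusted p = 0.00169). Without mock replicate 3, PR1 was at 5.98 and WRKY51 at 5.38. The 10 called clock genes moved in the same libraries.

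Among hormone lists, ethylene genes rose (13 of 19, with 6 not passing; median 0.62, camera adjusted p = 0.00549, or adjusted p = 0.515 with an estimated correlation), with ACS7, an enzyme gene of ethylene synthesis, at 2.60 (SE 0.21) and ERF104 at 1.51 (SE 0.15). Lists of other hormones did not pass with camera: jasmonate (6 of 23 higher, 11 lower, 6 not passing, adjusted p = 0.616), abscisic acid (4 of 14 higher, 5 lower, 5 not passing, adjusted p = 0.723) and auxin (4 of 14 higher, 3 lower, 7 not passing, adjusted p = 0.83). JAZ9, a jasmonate repressor gene, fell by 1.46 (SE 0.10), ABI1, a phosphatase gene of abscisic acid signalling, rose by 1.37 (SE 0.10) and IAA3 fell by 1.22 (SE 0.19). PDF1.2, a defensin gene, was not called (-0.22, SE 0.46, adjusted p = 0.711). Of 19 genes of camalexin and indole glucosinolates, 9 rose, 4 fell and 6 did not pass (median 0.30, camera adjusted p = 0.0209, or adjusted p = 0.525 with an estimated correlation, and adjusted p = 0.0614 without mock replicate 2). The transporter gene PEN3 rose by 2.39 (SE 0.09) and CYP71A12 by 5.07 (SE 0.29), while PAD3, the last enzyme gene of camalexin synthesis, was not called (-0.54, SE 0.27, adjusted p = 0.0979). Tryptophan and anthranilate synthesis did not pass (5 of 6 higher, 1 lower, camera adjusted p = 0.449). The 10 called clock genes moved beside these groups as well.

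Of 35 detoxification genes, 17 rose, 8 fell and 10 did not pass (median 0.72, camera adjusted p = 0.00654, or adjusted p = 0.409 with an estimated correlation). OPR1, an oxophytodienoate reductase gene beside a related copy, rose from 50.5 to 254 CPM (2.33, SE 0.07) and the factor gene NAC102 by 1.76 (SE 0.07), while GSTU5, a glutathione transferase gene in a tandem cluster, fell by 1.12 (SE 0.08). All 7 heat shock genes fell (median -3.05, camera adjusted p = 3.56e-05, or adjusted p = 0.196 with an estimated correlation), HSFA2 by 4.71 (SE 0.29). Genes of reactive oxygen did not pass (8 of 16 higher, 5 lower, 3 not passing, camera adjusted p = 0.0753), though the list was called without flg22 replicate 1 (adjusted p = 0.0472) and without flg22 replicate 3 (adjusted p = 0.0295). PRX71, a peroxidase gene, rose by 3.55 (SE 0.14). Chaperones of the endoplasmic reticulum did not pass (4 of 8 higher, 1 lower, 3 not passing, camera adjusted p = 0.588). The 10 called clock genes moved in the same libraries.

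Of 23 photosynthesis genes, 14 fell, 4 rose and 5 did not pass (median -0.23, camera adjusted p = 0.00125, or adjusted p = 0.636 with an estimated correlation); LHCB3 fell by 2.53 (SE 0.17). Of 14 phenylpropanoid genes, 9 fell and 5 did not pass (median -0.47, camera adjusted p = 0.00162, or adjusted p = 0.525 with an estimated correlation), with PAL2, an entry enzyme gene, down by a log2 change of -1.45 (SE 0.08). Of 14 iron deficiency genes, 8 fell, 1 rose and 5 did not pass (median -2.84, camera adjusted p = 0.0115, or adjusted p = 0.525 with an estimated correlation). BHLH39, a factor gene of the iron response beside the related BHLH38, fell by 4.82 (SE 0.32). This fixed list also holds FER1, a ferritin gene, so its counts alone do not give the direction of an iron response. Flavonoid genes did not pass (3 of 13 higher, 8 lower, 2 not passing, camera adjusted p = 0.316, and adjusted p = 0.0384 without flg22 replicate 3), nor did root markers (8 of 12 lower, 4 not passing, adjusted p = 0.126, and adjusted p = 0.0352 without mock replicate 1), stomatal lineage markers (1 of 4 higher, adjusted p = 0.827), cell division genes (1 of 8 higher, adjusted p = 0.921) or reference genes (3 of 10 higher, 2 lower, adjusted p = 0.83). In the clock list itself (6 of 11 higher, 4 lower, 1 not passing, camera adjusted p = 0.000109, or adjusted p = 0.186 with an estimated correlation), PRR5 rose by 4.82 (SE 0.16). Adjusted over the list alone, counts were the same except for camalexin (10 higher), early immunity (23 higher), cell division (0 called; 1 of 8 over all genes), flavonoid (9 lower), jasmonate (12 lower) and root markers (9 lower). None of the lists kept its call with an estimated correlation (0 of 14 called by camera). Fry, which does not compare a list with other genes, called 19.

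With 2-AA, 19 of 23 cell-surface receptor genes and 25 of 35 detoxification genes were higher than in mock (camera adjusted p = 1.49e-09 and 2.43e-17, or adjusted p = 0.186 and 0.112 with an estimated correlation). FRK1 rose to 203 ± 41.6 CPM (n = 3; log2 fold change 6.37, SE 0.35, edgeR adjusted p = 5.84e-09) and FLS2 to 58.6 CPM (1.83, SE 0.11, adjusted p = 1.61e-08). WRKY30, an early immune factor gene, rose by 5.33 (SE 0.26, adjusted p = 2.19e-09) and OPR1 by 4.08 (SE 0.08, adjusted p = 4.37e-12), from 50.5 to 854 CPM. The lignin enzyme gene 4CL1 fell by 2.85 (SE 0.11, adjusted p = 3.49e-10), from 287 to 39.9 CPM. The morning clock gene CCA1 fell by 5.6 (SE 0.30, adjusted p = 4.41e-09; -6.32 without 2-AA replicate 3), and PR1 was not called (0.20, SE 0.99, adjusted p = 0.872).

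In all, edgeR called 13103 of 21059 genes (62.2%), 6560 higher and 6543 lower with 2-AA than in mock, and 2119 and 2497 of them by at least 2-fold. The nitrate transporter gene NRT2.5 rose by 7.63 (SE 0.49), ATGLR1.2, a glutamate receptor-like gene, by 7.13 (SE 0.51), COR27 by 7.46 (SE 0.38) and FKF1 by 7.12 (SE 0.16). GSTU11, a glutathione transferase gene beside a related copy and with 0 counts in all mock libraries, was at least 164.5-fold higher. GBSS1 fell by 6.46 (SE 0.26), LHY by 6.21 (SE 0.38) and BBX16 by 5.83 (SE 0.40). COR27 was at least 1080-fold higher without mock replicate 3, and LHY and BBX16 at -7.07 and -6.48 without 2-AA replicate 3. Without mock 3, flg22 2 and 2-AA 2 the count was 11725, and with them as a term 13156.

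Of 35 detoxification genes, 25 rose and 10 did not pass (median 2.11, camera adjusted p = 2.43e-17, or adjusted p = 0.112 with an estimated correlation). NAC102 rose by 2.67 (SE 0.07). The glucosyltransferase genes UGT73B4 and UGT73B5 rose by 4.06 (SE 0.15) and 3.10 (SE 0.14), values that are uncertain because their annotated spans overlap. All 8 chaperones of the endoplasmic reticulum rose (median 0.87, camera adjusted p = 0.000944, or adjusted p = 0.403 with an estimated correlation), with BIP3 at 2.58 (SE 0.22) and ERDJ3B at 1.15 (SE 0.08). Of 16 genes of reactive oxygen, 12 rose, 2 fell and 2 did not pass (median 0.70, camera adjusted p = 0.00346, or adjusted p = 0.409 with an estimated correlation); PRX71 rose by 4.61 (SE 0.14), and RBOHD was not called (-0.13, SE 0.11, adjusted p = 0.307), but was without mock replicate 2 (-0.25, adjusted p = 0.0293). All 7 heat shock genes fell (median -2.39, camera adjusted p = 0.00337, or adjusted p = 0.402 with an estimated correlation), HSP70 by 3.03 (SE 0.19). In the same libraries, 10 of 11 clock genes were called, with 6 higher and 4 lower.

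Of 23 cell-surface receptors and co-receptors, 19 rose, 1 fell and 3 did not pass (median 1.23, camera adjusted p = 1.49e-09, or adjusted p = 0.186 with an estimated correlation), with IOS1 at 4.04 (SE 0.18), EFR at 2.88 (SE 0.11) and BAK1 at 0.90 (SE 0.07). Of 13 cysteine-rich receptor-like kinases, 11 rose and 2 did not pass (median 2.88, camera adjusted p = 2.99e-07, or adjusted p = 0.192 with an estimated correlation). All 10 intracellular receptors and helpers rose (median 1.16, camera adjusted p = 1.32e-06, or adjusted p = 0.311 with an estimated correlation), RPM1 by 1.88 (SE 0.11). Of 29 early immunity markers, 21 rose, 3 fell and 5 did not pass (median 2.03, camera adjusted p = 2.8e-06, or adjusted p = 0.403 with an estimated correlation), including PUB22 (3.15, SE 0.18), CYP81F2 (2.83, SE 0.17) and NHL10 (2.18, SE 0.36). Of 29 WRKY factors, 23 rose, 1 fell and 5 did not pass (median 1.52, or 1.43 with a member at its bound, camera adjusted p = 1.17e-07, or adjusted p = 0.402 with an estimated correlation), with WRKY29 at 1.56 (SE 0.20) and WRKY33 at 1.78 (SE 0.17). Of 24 salicylic acid genes, 14 rose, 4 fell and 6 did not pass (median 0.93, camera adjusted p = 0.00892, or adjusted p = 0.487 with an estimated correlation). CBP60G rose by 3.77 (SE 0.23) and ICS1 by 0.97 (SE 0.24; adjusted p = 0.0717 against 1.5-fold). The value of PR1 changed sign without mock replicate 1 (-0.31), mock replicate 2 (-0.21) or 2-AA replicate 3 (-2.13); without the 3 organelle-rich libraries it was 2.82 and called (adjusted p = 0.0196), and ICS1 was not (0.74, adjusted p = 0.0554). The 10 called clock genes moved beside these groups.

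Of 19 ethylene genes, 14 rose and 5 did not pass (median 0.51, camera adjusted p = 0.00125, or adjusted p = 0.416 with an estimated correlation); ACS7 rose by 3.87 (SE 0.21). With camera, jasmonate (7 of 23 higher, 14 lower, 2 not passing, adjusted p = 0.738), abscisic acid (5 of 14 higher, 4 lower, 5 not passing, adjusted p = 0.454) and auxin (5 of 14 higher, 3 lower, 6 not passing, adjusted p = 0.679) did not pass. GH3.3, an auxin-conjugating enzyme gene, rose by 2.16 (SE 0.18) and JAZ9 fell by 1.76 (SE 0.10). PDF1.2 fell by 1.45 (SE 0.49, adjusted p = 0.0204), a call that ended without mock replicate 3 (-0.67), 2-AA replicate 2 (-1.30) or the 3 organelle-rich libraries (-0.51). It also ended with limma-voom (adjusted p = 0.1), robust dispersions (adjusted p = 0.0632) and the test against 1.5-fold (adjusted p = 0.0871). Camalexin and indole glucosinolate genes did not pass (7 of 19 higher, 6 lower, 6 not passing, camera adjusted p = 0.085), but did without mock replicate 3 (adjusted p = 0.0462) and without 2-AA replicate 3 (adjusted p = 0.043). PEN3 rose by 2.76 (SE 0.09), and PAD3 was not called (-0.35, SE 0.26, adjusted p = 0.268). Tryptophan and anthranilate synthesis did not pass (1 of 6 higher, 1 lower, 4 not passing, adjusted p = 0.961). Clock genes differed in the same libraries.

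Of 14 phenylpropanoid genes, 12 fell and 2 did not pass (median -1.53, camera adjusted p = 5.59e-10, or adjusted p = 0.263 with an estimated correlation), PAL2 by 2.40 (SE 0.08) and CCoAOMT1 by 1.71 (SE 0.09). Of 23 photosynthesis genes, 17 fell and 6 did not pass (median -0.57, camera adjusted p = 7.12e-05, or adjusted p = 0.568 with an estimated correlation); LHCB4.2 fell by 2.81 (SE 0.15). Iron deficiency genes did not pass (2 of 14 higher, 9 lower, 3 not passing, camera adjusted p = 0.063), but did without 2-AA replicate 3 (adjusted p = 0.00398); F6'H1, which makes coumarins, fell by 2.35 (SE 0.11). Flavonoid genes (2 of 13 higher, 8 lower, 3 not passing, adjusted p = 0.331), root markers (6 of 12 lower, 6 not passing, adjusted p = 0.289), stomatal lineage markers (1 of 4 higher, 2 lower, adjusted p = 0.936), cell division genes (2 of 8 lower, adjusted p = 0.827) and reference genes (3 of 10 higher, 2 lower, adjusted p = 0.886) did not pass. The clock list was called higher (6 of 11 higher, 4 lower, 1 not passing, camera adjusted p = 0.000385, or adjusted p = 0.186 with an estimated correlation), with ELF4 up by 4.72 (SE 0.12). Camera tests for a shift one way, while these members went both ways (mean log2 fold change -0.0475). Adjusted over the list alone, counts were the same except for cysteine-rich kinases (12 higher), salicylic acid (15 higher) and detoxification (26 higher). None of the 14 lists called kept its call with an estimated correlation (0 by camera). Fry, which does not compare a list with other genes, called 20.

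**Figure D1:**
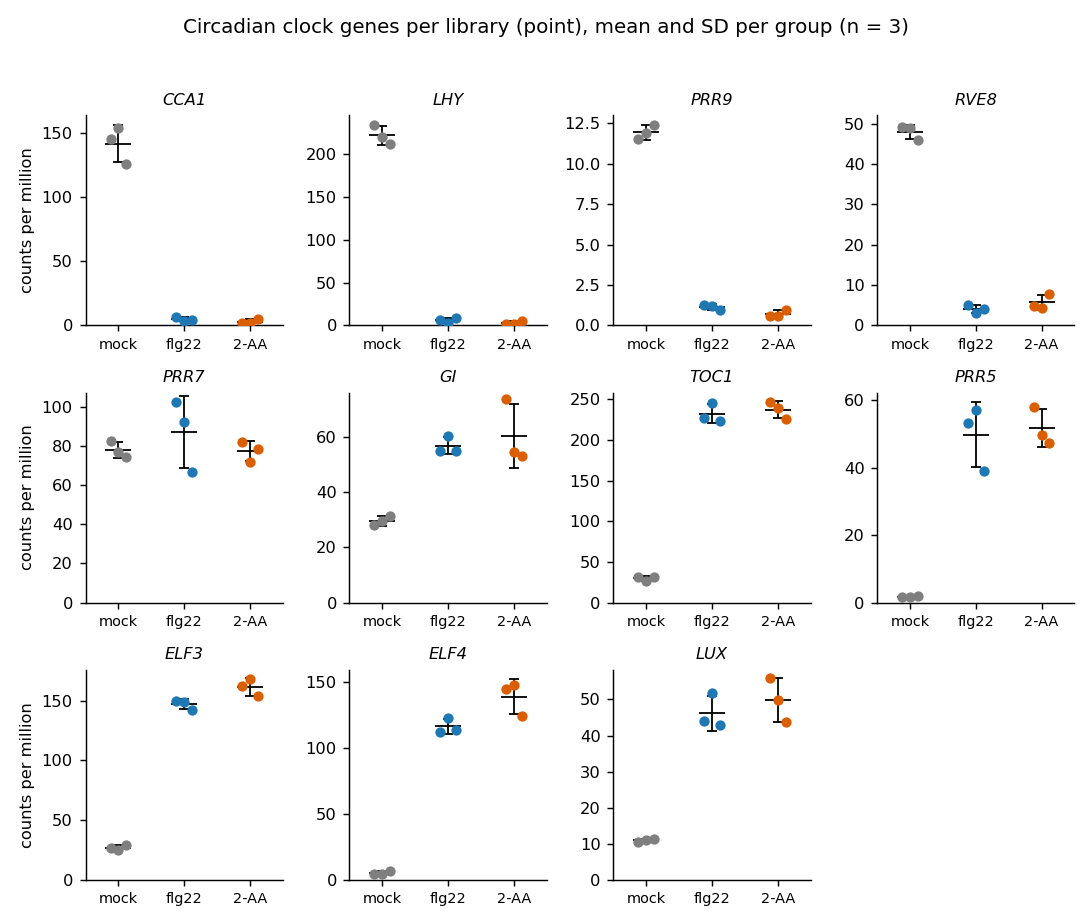
Circadian clock genes in each library (points), with the mean and SD of each group (n = 3), in CPM.

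Set directly against flg22, 2-AA gave higher values for 28 of 35 detoxification genes and 7 of 8 endoplasmic reticulum chaperones, and lower ones for 9 of 24 salicylic acid and 12 of 14 phenylpropanoid genes. With an estimated correlation, detoxification kept its camera call (adjusted p = 0.00359) and the other lists lost theirs (adjusted p = 0.165, 0.263 and 0.172). GSTU22, a glutathione transferase gene in a tandem cluster, was at 16.1 ± 4.26 CPM with 2-AA and 1.52 ± 0.457 with flg22 (mean ± SD, n = 3 each; log2 difference 3.40, SE 0.25, edgeR adjusted p = 1.93e-06). BIP3, a chaperone gene of the unfolded protein response, was higher by 2.52 (SE 0.22, adjusted p = 7.54e-06). PR1 was at 0.766 ± 1.08 CPM with 2-AA and 10.2 ± 4.35 with flg22 (-3.67, SE 0.85, adjusted p = 0.0101, adjusted p = 0.0947 with robust dispersions and adjusted p = 0.0506 against 1.5-fold), and PR2, a glucanase gene, was lower by a log2 difference of -4.97 (SE 0.42, adjusted p = 6.23e-06). PR1 was at -6.01 without 2-AA replicate 3 and PR2 at -5.98 without 2-AA replicate 1. 4CL1 was lower (-1.73, SE 0.11, adjusted p = 5e-07). Neither FRK1 (0.51, SE 0.26, adjusted p = 0.216) nor FLS2 (0.17, SE 0.11, adjusted p = 0.323) was called, though FRK1 was without flg22 replicate 1 (0.85, adjusted p = 0.033).

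In all, edgeR called 3317 of 21059 genes (15.8%), 1656 higher and 1661 lower with 2-AA, and 353 and 312 of them by at least 2-fold. The even split depended on the setting. Against a 1.5-fold change 287 were higher and 186 lower, and with upper-quartile scaling 42.2% of 3414 called genes were higher. AT1G60750, annotated as an oxidoreductase, was higher by 5.58 (SE 0.49), EHB1 by 4.21 (SE 0.21), the cytochrome gene CYP89A6 by 3.64 (SE 0.35) and the transporter gene ABCG40 by 3.41 (SE 0.13). LURP1, a defence gene, was lower (-5.52, SE 0.73), as were PCR1 (-5.22, SE 0.51) and PCC1 (-3.63, SE 0.42). AT4G19750, with 0 counts in all 2-AA libraries, was at least 157-fold higher with flg22 (at least 82.4-fold without flg22 replicate 1, where AT1G60750 was at 6.8). LURP1 was at -6.48 without 2-AA replicate 3 and PCR1 at -5.99 without 2-AA replicate 2. The 1661 lower genes became 1096 without 2-AA replicate 1 and 1071 without 2-AA replicate 2, and the 312 lower by at least 2-fold became 138 with a filter of 5 CPM in 3 libraries and 169 against 1.5-fold. The total was 2091 without mock 3, flg22 2 and 2-AA 2, and 3594 with these as a term.

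Of 35 detoxification genes, 28 were higher with 2-AA and 7 did not pass (median 1.5, camera adjusted p = 9.74e-69, or adjusted p = 0.00359 with an estimated correlation). OPR1 was higher by 1.75 (SE 0.07), GSTU19 by 2.25 (SE 0.12) and GSTU1 by 2.33 (SE 0.14), both transferase genes that lie in tandem clusters. Of 8 endoplasmic reticulum chaperones, 7 were higher and 1 lower (median 0.77, camera adjusted p = 1.53e-13, or adjusted p = 0.165 with an estimated correlation). Of 16 genes of reactive oxygen, 9 were higher, 1 lower and 6 did not pass (median 0.38, camera adjusted p = 0.000255, or adjusted p = 0.336 with an estimated correlation); the redox-responsive factor gene ZAT12 was higher by 1.99 (SE 0.18). Of 7 heat shock genes, 3 were higher and 4 did not pass (median 0.36, camera adjusted p = 0.00696, or adjusted p = 0.406 with an estimated correlation). RBOHD was higher by 0.39 (SE 0.11, adjusted p = 0.0265), but was not called without any 1 of the flg22 libraries (0.38, 0.39 and 0.39 without replicates 1, 2 and 3). Nor was it called without 2-AA replicate 1 (0.36), 2-AA replicate 2 (0.32) or the 3 organelle-rich libraries (0.33). It was not called against 1.5-fold either, which an estimate below 1.5-fold could not be.

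Of 24 salicylic acid genes, 9 were lower with 2-AA, 1 was higher and 14 did not pass (median -0.66, camera adjusted p = 5.82e-06, or adjusted p = 0.263 with an estimated correlation). DMR6, a salicylic acid hydroxylase gene, was lower (-1.29, SE 0.13), as were the factor genes WRKY70 (-2.06, SE 0.22) and WRKY54 (-2.0, SE 0.24), and ICS1 was not called (-0.15, SE 0.24, adjusted p = 0.729). Of 29 early immunity markers, 11 were higher, 2 lower and 16 did not pass (median 0.39, camera adjusted p = 0.000192, or adjusted p = 0.487 with an estimated correlation). WRKY30 was higher by 2.78 (SE 0.21), WRKY22 by 1.79 (SE 0.18) and CYP81F2 by 1.00 (SE 0.16; adjusted p = 0.0871 against 1.5-fold), while NHL10 (0.65, SE 0.33, adjusted p = 0.215) and WRKY29 (0.09, SE 0.19, adjusted p = 0.805) were not called. WRKY33 was not called (0.49, SE 0.16, adjusted p = 0.0569), but was with DESeq2 (adjusted p = 0.0214), limma-voom (adjusted p = 0.0199), without mock replicate 2 (adjusted p = 0.0481), without mock replicate 3 (adjusted p = 0.0033), with no low-count filter (adjusted p = 0.0307) and with only the groups compared (adjusted p = 0.00575). It was also called without the 3 organelle-rich libraries (adjusted p = 0.0195) and with these as a term (adjusted p = 0.0185). The WRKY list did not pass (8 of 29 higher, 7 lower, 14 not passing, camera adjusted p = 0.0888), but was called without mock replicate 3 (adjusted p = 0.0329), flg22 replicate 1 (adjusted p = 0.0274) or 2-AA replicate 3 (adjusted p = 0.026), and with only the groups compared (adjusted p = 0.0336).

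Cell-surface receptors did not pass as a list (7 of 23 higher, 2 lower, 14 not passing, camera adjusted p = 0.0678), nor did intracellular receptors (3 of 10 higher, 7 not passing, adjusted p = 0.085). Without flg22 replicate 1 these were called (adjusted p = 0.00903 and 0.0251), and likewise without 2-AA replicate 3 (adjusted p = 0.0357 and 0.0481). IOS1 was higher with 2-AA by 0.95 (SE 0.16) and EFR by 0.66 (SE 0.10), calls that ended against 1.5-fold (adjusted p = 0.144 and 1), and the wall-associated kinase gene WAK1, in a tandem cluster, was lower (-1.29, SE 0.23). BAK1 was higher by 0.28 (SE 0.07, adjusted p = 0.0147), a call that ended without flg22 replicate 3 (0.24), 2-AA replicate 1 (0.26) or 2-AA replicate 2 (0.25), or without the 3 organelle-rich libraries (0.24). BAK1 was not called against 1.5-fold either, which an estimate below 1.5-fold could not be. Cysteine-rich kinases went both ways (2 of 13 higher, 2 lower, 9 not passing, camera adjusted p = 0.753), with CRK11 higher by 1.23 (SE 0.16) and CRK4 lower (-3.22, SE 0.29).

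Of 14 phenylpropanoid genes, 12 were lower and 2 did not pass (median -0.80, camera adjusted p = 1.99e-21, or adjusted p = 0.172 with an estimated correlation), among them 4CL2 (-1.79, SE 0.12), C4H (-1.14, SE 0.11) and PAL2 (-0.95, SE 0.08). Of 23 photosynthesis genes, 7 were lower and 16 did not pass (median -0.17, camera adjusted p = 0.00509, or adjusted p = 0.677 with an estimated correlation and adjusted p = 0.082 with fry); among these, RBCS2B and RBCS3B are near-identical neighbours whose reads are hard to assign. Iron deficiency genes did not pass (5 of 14 higher, 3 lower, 6 not passing, camera adjusted p = 0.206), but did without 2-AA replicate 1 (adjusted p = 0.0327) or 2-AA replicate 2 (adjusted p = 0.015). BHLH39 was higher with 2-AA by 4.23 (SE 0.33) and F6'H1 lower (-2.14, SE 0.11). Abscisic acid genes were called (4 of 14 higher, 10 not passing; median 0.61, camera adjusted p = 0.000219, or adjusted p = 0.172 with an estimated correlation), with RD29A, a drought gene, higher by 0.95 (SE 0.12). Tryptophan and anthranilate synthesis was called lower (3 of 6 lower, 3 not passing; median -0.17, camera adjusted p = 0.0209, or adjusted p = 0.525 with an estimated correlation, and adjusted p = 0.124 without 2-AA replicate 3). Ethylene genes were called (4 of 19 higher, 15 not passing; median 0.14, camera adjusted p = 0.0471, or adjusted p = 0.61 with an estimated correlation), with the synthase gene ACS6 higher by 1.27 (SE 0.15). Among settings that ended this call were omission of flg22 replicate 3 (adjusted p = 0.178) or 2-AA replicate 2 (adjusted p = 0.131) and fry (adjusted p = 0.0626).

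With camera, auxin (2 of 14 higher, 1 lower, adjusted p = 0.562), jasmonate (2 of 23 higher, 2 lower, adjusted p = 0.849), camalexin and indole glucosinolates (4 of 19 higher, 5 lower, adjusted p = 0.45), flavonoids (1 of 13 higher, adjusted p = 0.91), root markers (2 of 12 higher, 1 lower, adjusted p = 0.588), stomatal markers (1 of 4 lower, adjusted p = 0.331), cell division (1 of 8 lower, adjusted p = 0.289) and reference genes (1 of 10 higher, adjusted p = 0.886) did not pass. CYP71A12 was lower with 2-AA (-1.63, SE 0.22), GH3.3 was higher by 1.80 (SE 0.18), and PAD3 (0.19, SE 0.27, adjusted p = 0.701) was not called. PDF1.2 was not called either (-1.23, SE 0.49, adjusted p = 0.117), but was without mock replicate 1 (adjusted p = 0.047), without mock replicate 3 (adjusted p = 0.0417) and with only the groups compared (adjusted p = 0.0283). Of 11 clock genes, edgeR called 0 between the treatments (5 at unadjusted p under 0.05; 0 by DESeq2; 1 by limma-voom, camera adjusted p = 0.961). Adjusted over the list alone, counts were the same except for camalexin (6 lower), early immunity (12 higher, 3 lower), ethylene (1 lower), heat shock (4 higher), iron (8 higher), photosynthesis (8 lower), reactive oxygen (2 lower), salicylic acid (2 higher, 10 lower), WRKY (12 higher, 8 lower) and detoxification (30 higher). Of 11 lists called, 1 (detoxification) kept its call with an estimated correlation. With fry 10 lists were called, without ethylene and photosynthesis and with auxin (adjusted p = 0.019).

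**Figure D2:**
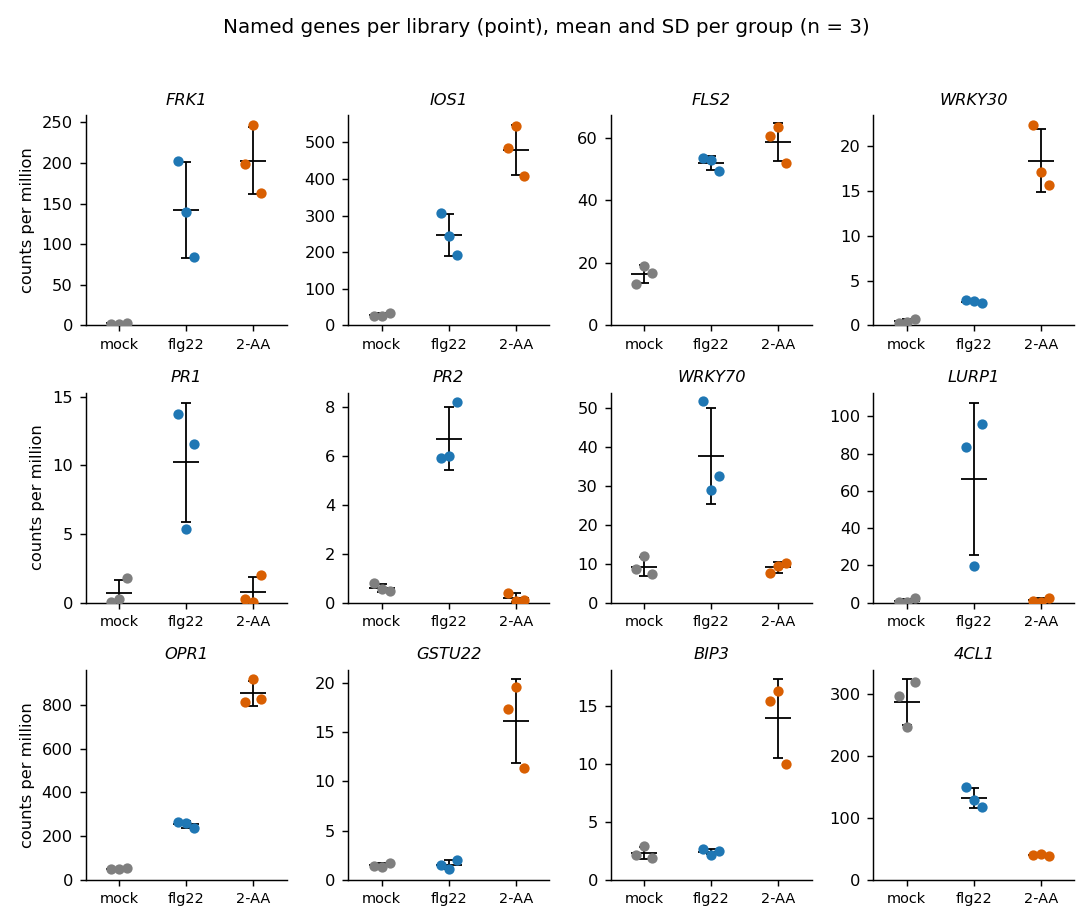
Genes named in the text in each library (points), with the mean and SD of each group (n = 3), in CPM.

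**Figure D3:**
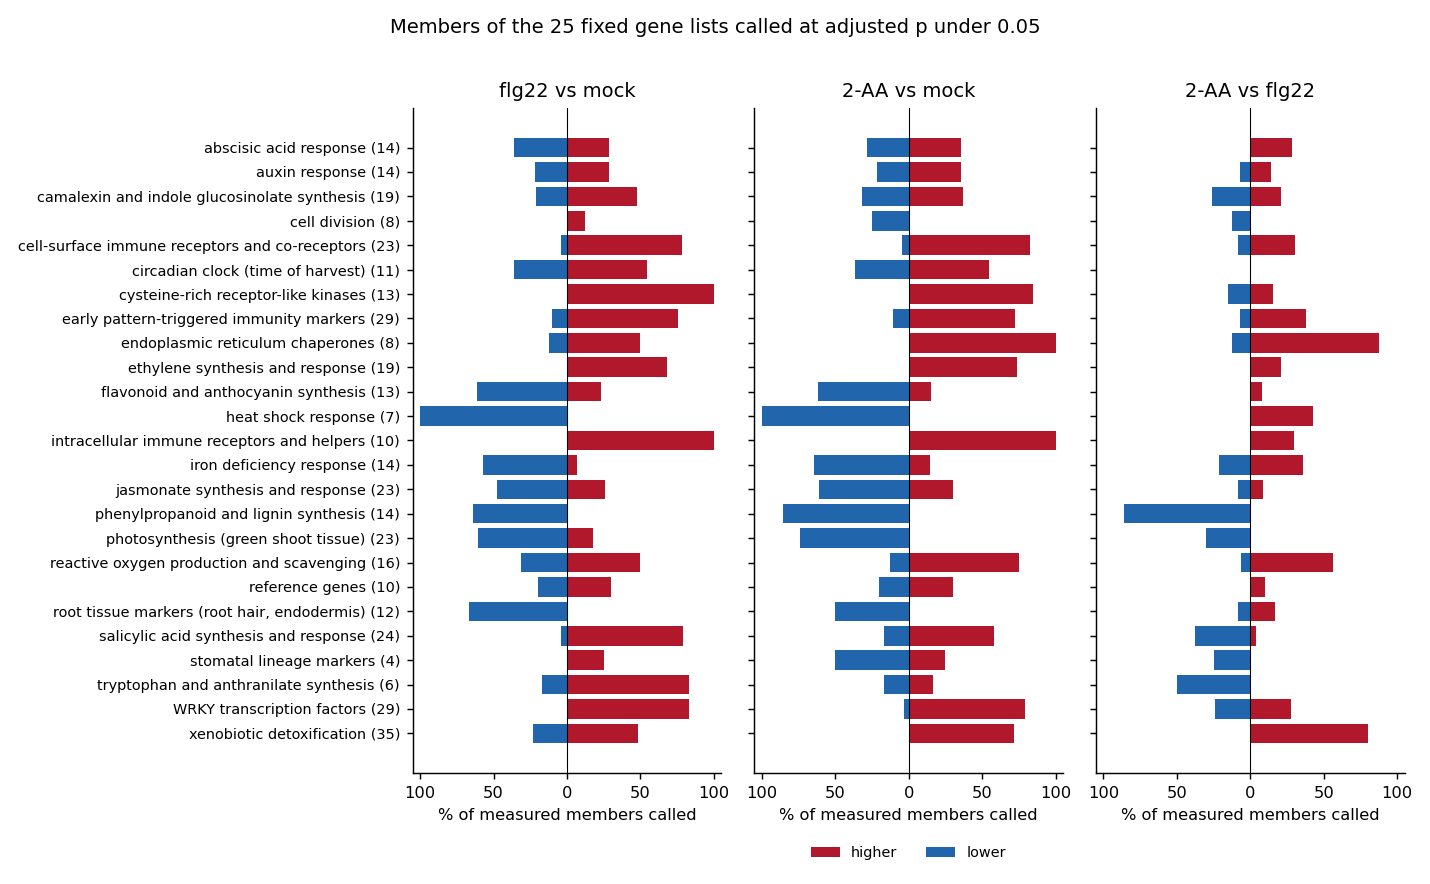
Percent of the measured members of each fixed list called higher (red) or lower (blue) in each comparison, at edgeR adjusted p under 0.05.

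The changes against mock were largely shared. In the same direction, 10707 genes were called with both treatments, 5381 higher and 5326 lower, and 109 in opposite directions. Among the shared genes, GSTU11 was at least 112-fold and at least 164.5-fold higher than mock with flg22 and 2-AA, and NIMIN1, which encodes a partner of NPR1, at least 45.0-fold and at least 22.8-fold higher. WAKL10, a wall-associated kinase-like gene, was at least 31.5-fold and at least 58.3-fold higher. In opposite directions, GLR2.3, a glutamate receptor-like gene, rose with flg22 by 2.3 (SE 0.32, edgeR adjusted p = 3.73e-05) and fell with 2-AA by 1.71 (SE 0.41, adjusted p = 0.00254), and NIT2, a nitrilase gene, fell with flg22 by 1.54 (SE 0.25) and rose with 2-AA by 0.92 (SE 0.23; adjusted p = 0.0883 against 1.5-fold, and 0.57 without 2-AA replicate 3). PR2 rose with flg22 by 3.47 (SE 0.36) and fell with 2-AA by 1.5 (SE 0.49, adjusted p = 0.0164); the second call ended without mock replicate 1 (-1.24), 2-AA replicate 2 (-1.16), 2-AA replicate 3 (-1.22) or the 3 organelle-rich libraries (-1.30). It also ended with only the groups compared (adjusted p = 0.0588) and against 1.5-fold (adjusted p = 0.0711), and the value was -2.51 without 2-AA replicate 1. The 10707 genes were 86.0% of those called with flg22 and 81.7% of those called with 2-AA.

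Independent lists of these sizes would share 3875 genes in the same direction. Unchanged groups compared with 1 shared mock group, all drawn from the mock means, shared 0.08 on average (highest 1 in 50 simulations). These draws hold only random spread between libraries, not the real mock libraries. Any feature of the 3 real mock libraries enters both comparisons and is absent from these draws. The 3 libraries are too few to split, and a split would keep a feature common to all 3. The part of such a feature in the excess was not measured. Of the shared genes, 1847 (17.3%) were also called between 2-AA and flg22 and 8860 (82.7%) were not, which does not show equal levels. Called higher with 2-AA than in both other groups were 1221 genes, and lower 918. Called higher with flg22 than in both others were 718, and lower 449. Across the 21059 genes, which are not independent replicates, log2 fold changes against mock had a Pearson correlation of 0.873 (simulated 0.494, range 0.469 to 0.524) and a covariance of 0.974 (simulated 0.0348).

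**Figure D4:**
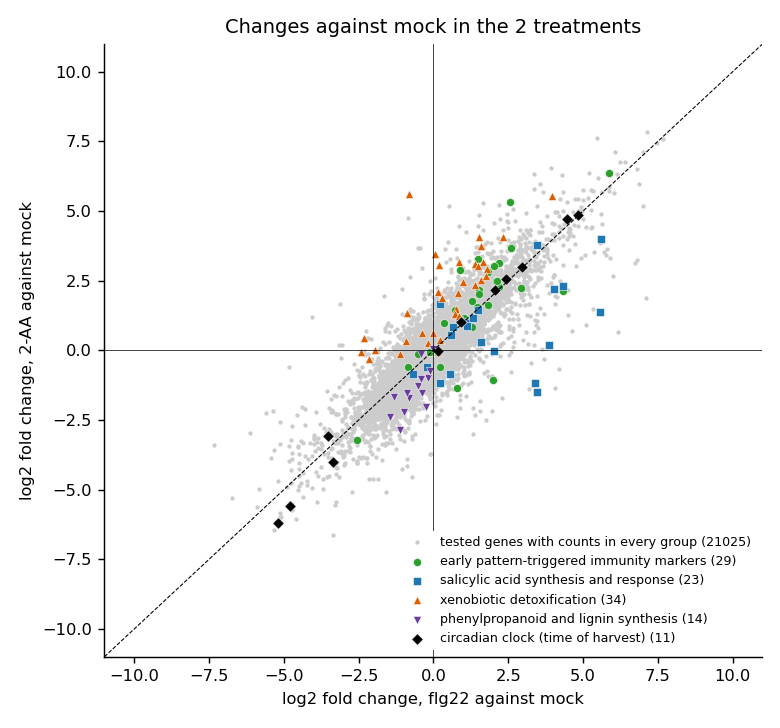
Log2 fold changes against mock with flg22 and with 2-AA for 21025 genes, leaving out 34 genes with 0 counts in a group; 5 fixed lists are coloured and the dashed line marks equal change.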

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

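Chosen after the data were seen were 2 settings: omission of mock 3, flg22 2 and 2-AA 2, and these libraries as a term in the fit. Values of named genes kept direction and side of the threshold in 3412 cases, lost a call in 36, gained one in 14 and changed sign in 12. For lists these numbers were 960, 45, 30 and 15. Most named genes were picked for large changes or small p in these same libraries, so their stability is partly built in. Over all called genes, 2-AA against flg22 kept from 64.64% (without 2-AA replicate 2) to 96.77% (without mock replicate 3) of its calls with 1 library left out. DESeq2 called 12488, 13095 and 3755 genes (flg22 against mock, 2-AA against mock, 2-AA against flg22) and limma-voom 12566, 13164 and 3355; of the reported calls DESeq2 shared 98.98, 99.01 and 99.19% in the same direction. With 1 library left out the counts ran from 11281 to 12463, from 12048 to 13159 and from 2217 to 3391. Against a 1.5-fold change, a stricter hypothesis by construction, they were 4836, 5586 and 473. Without mock 3, flg22 2 and 2-AA 2, which leaves fewer libraries, 2-AA against flg22 gave 2091. Library numbers did not pair the libraries (r between -0.134 and 0.188 for equal numbers), and with a replicate block the counts were 12264, 12918 and 3082, iron deficiency was called for 2-AA against mock (adjusted p = 0.0461) and ethylene was not for 2-AA against flg22 (adjusted p = 0.0608). Lists called with an estimated correlation were 0 and 0 against mock and 1 for 2-AA against flg22. The preset correlation was 0.01, and the estimates ran from -0.058 (auxin) to 0.659 (photosynthesis), both for 2-AA against mock. Camera allows for more spread where the correlation is higher, so p-values with the preset are too small for lists well above it. With an estimated correlation it also uses only 6 residual degrees of freedom, which raises p-values at any correlation. The abscisic acid list for 2-AA against flg22 had an estimate of only 0.022, yet its unadjusted camera p went from 6.42e-05 to 0.00944. A lost call therefore does not by itself show correlated genes. How much of each lost call either part accounts for was not tested. The overlap at 2-fold or more in both was 3231. The correlation of fold changes was 0.7364 with no filter, 0.9231 at 5 CPM in 3 libraries, 0.8894 for genes called in either comparison, and 0.8525 to 0.881 with 1 library left out, shifts whose cause was not tested.

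Signs turned only for results that were not called. With 1 library left out, the adjusted p of such lists ran, for flg22 against mock, from 0.796 to 0.982 (cell division). For 2-AA against mock it ran from 0.414 to 0.982 (jasmonate), 0.83 to 0.98 (stomatal) and 0.847 to 0.99 (tryptophan). For 2-AA against flg22 it ran from 0.577 to 0.995 (clock), 0.357 to 0.83 (cysteine-rich kinases), 0.511 to 0.923 (flavonoid) and 0.753 to 0.95 (jasmonate). The clock list also turned with only the groups compared (0.958) and the jasmonate list with the replicate block (0.82). Log2 differences between the treatments ran from -0.42 to 0.125 for ICS1 (above 0 without flg22 1 or 2-AA 3), -0.0351 to 0.38 for PAD3 (under 0 without 2-AA 1) and -0.1069 to 0.24 for WRKY29 (under 0 without flg22 3, at -0.099 without 2-AA 2, and -0.0213 without mock 3, flg22 2 and 2-AA 2). Against mock, log2 fold changes of PR1 with 2-AA ran from -2.1257 (without 2-AA 3) to 2.31, with -0.3098 without mock 1 and -0.2069 without mock 2. Beyond that range, PR1 was at 2.82 without mock 3, flg22 2 and 2-AA 2. Those of PDF1.2 with flg22 ran from -0.61 to 0.5675 (without mock 3), with 0.0776 without flg22 1 and 0.3517 without mock 3, flg22 2 and 2-AA 2. For these changes the cause was not tested. PR1 was at 0.766 CPM on average with 2-AA, where counts are few, and its direction there was not settled.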

Other observations

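The tests of gene families and of explanations in this part were chosen after the results were seen; the clock list and the comparisons were fixed before the data were examined. The clock test of the detoxification pattern and the left-out-library test of the salicylic acid pattern replaced earlier forms of those tests. Genes were grouped into 314 families of at least 10 tested genes by the product names of the reference annotation, and tested with camera over 942 tests, which called 22 families for flg22 against mock, 23 for 2-AA against mock and 19 for 2-AA against flg22. With an estimated correlation each call named here was lost (adjusted p = 0.775, or 0.777 for expansins). Of 278 ribosomal protein genes, edgeR called 221 lower and 40 higher with flg22 (median log2 fold change -0.90, camera adjusted p = 1.61e-24) and 225 lower and 32 higher with 2-AA (-1.02, adjusted p = 1.1e-29). Of 23 genes named as eukaryotic translation initiation factors, 19 and 20 were lower (adjusted p = 4.36e-07 and 4.77e-07), while 20 other initiation factor genes were not called as a group (adjusted p = 0.748 and 0.68). Of 19 genes annotated as DEA(D)-box helicases, 16 and 17 were lower (adjusted p = 2.83e-08 and 5.54e-08). Clock genes differed in the same libraries, with 10 of 11 called against mock.

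Of 26 arabinogalactan proteins, 19 were lower with flg22 and 20 with 2-AA (camera adjusted p = 9.68e-05 and 3.56e-05), of 18 expansins 15 and 15 (0.0118 and 0.00772), and of 12 plasma membrane aquaporins 10 and 12 (0.000531 and 6.19e-05). Of 118 genes annotated as disease resistance proteins, 92 were higher and 3 lower with flg22 (median 0.86, adjusted p = 9.07e-11) and 85 and 3 with 2-AA (0.77, adjusted p = 1.33e-08). Between 2-AA and flg22, 11 of 25 tau-class glutathione transferases were higher with 2-AA and 1 lower (camera adjusted p = 4.68e-15). Tau-class genes higher with 2-AA, such as GSTU1, GSTU5, GSTU19 and GSTU22, are also in the fixed detoxification list. This family call therefore repeats part of that list and is not separate evidence. All calls of families in this paragraph were lost with an estimated correlation as well, as given above. The clock genes differed beside each contrast with mock.

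Between mock and each treatment, 10 of 11 clock genes differed. Scaling moves all genes of a library the same way, so it cannot by itself lower 4 morning genes and raise 6 evening genes. Other scalings moved the median of all genes by at most 0.0434, while the 10 phased clock genes had a median absolute log2 change of 3.44. A mock harvest at another hour is consistent with all 10 of 10 phased genes, 4 morning genes lower and 6 evening genes higher with each treatment. An effect of each treatment on the clock itself cannot be told apart from it: 1 of 11 clock genes was not called, and the hour of harvest is not given in the sources used here. Either may account for part of the changes shared by the treatments against mock, and how much was not tested.

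With 2-AA, 28 of 35 detoxification genes were higher than with flg22. Reads shared between tandem paralogs are argued against as the whole cause, as far as gene names show families. The 11 members with no tested gene of like product name or symbol within 50 kb had a median log2 difference of 1.01, with 8 higher. Tandem copies named otherwise would be missed, and paralogs elsewhere in the genome were not tested. Without the organelle-rich 2-AA replicate 2, the same 28 members were called higher. A different hour of harvest between these groups stays open: the median absolute difference of the 11 clock genes was 0.171, but the morning genes LHY, CCA1, PRR9 and RVE8 had log2 differences of -1.02, -0.79, -0.63 and 0.46 (5 of 11 at unadjusted p under 0.05, 0 called by edgeR, 0 by DESeq2 and 1 by limma-voom). An action of 2-AA itself, a foreign compound to the plant, may be the source and was not tested.

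Of 24 salicylic acid genes, 9 were lower with 2-AA than with flg22, 1 was higher and 14 did not pass (camera adjusted p = 5.82e-06, or adjusted p = 0.263 with an estimated correlation). No single flg22 library carried this, as the median of the 24 members was -0.66 with all libraries and came nearest to 0 at -0.459 when flg22 replicate 1 was left out. For the early immunity markers, a weaker response to 2-AA is argued against by the list median, which was 0.386 higher with 2-AA. Of the 29 markers, 11 were higher, 2 lower and 16 did not pass (camera adjusted p = 0.487 with an estimated correlation). Cell-surface receptors leaned the same way (7 of 23 higher, 2 lower). Cysteine-rich kinases (2 of 13 higher, 2 lower) and WRKY factors (8 of 29 higher, 7 lower) went both ways. The immune response as a whole was therefore not judged. A different time course of the 2 responses could give the same pattern, and it was not tested, since the duration of treatment is not given in the sources used here.

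For each comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes with edgeR as the real grouping. The real splits gave 12253 (flg22 against mock), 13023 (2-AA against mock) and 3056 (2-AA against flg22) genes, and the highest of the other splits 0 in each, or 277, 235 and 932 at an unadjusted p under 0.05; no other tool was run on these. Each other split mixed libraries of both real groups on each side. The difference between the groups then widened the spread within a side, so low counts were built in. The gap between the real and the other splits therefore does not measure chance. With 10 splits the share is never under 0.1.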
